A study of Mus musculus with 13 samples.

How the data were processed

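The series covers sorted CD4+CD8+ double-positive thymocytes, the stage of T cell development in the thymus that carries both coreceptors. The cells were wild type or knockout (KO) for Rad21, a subunit of the ring-shaped cohesin complex. The sample titles do not say how, or in which cells of the mouse, the gene was deleted. RNA-seq was made from 2 wild type and 2 Rad21 KO samples. ChIP-seq was made from wild type cells for Rad21, for the cohesin loader subunit NIPBL and for the Mediator subunit Med1, with 1 library per protein. The labels also list 2 ChIP input libraries and 4 Hi-C libraries, which were not analysed here. In all, the labels list 13 samples.

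Per the labels' protocols, total RNA was depleted of ribosomal RNA with a RiboMinus kit and made into Illumina TruSeq libraries. The authors deposited the RNA-seq values as count equivalents per Ensembl gene, read here as estimated counts: all are whole numbers, and the totals differ between libraries. The genome build is mm9 per the submitters' processing notes. The aligner, the counting program and the use of strand are not given in the sources used here, so genes that overlap another gene or an antisense transcript, and genes with near-identical copies, have uncertain counts. No column of per-sample values was left unused. The knockout columns spell the gene name with a digit missing and were matched to their samples by the rest of the name.

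Symbols were found for 17342 of the 17849 gene identifiers. Total counts were 9384505 and 6914654 in the 2 Rad21 KO libraries and 6633506 and 6500819 in the 2 wild type libraries. A count of 3, taken as the floor per library, corresponded to 0.410 to 0.417 CPM. Each library counted as a sample, as the labels list it. Replicate libraries of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 85.9 for the knockout pair and 7.43 for the wild type pair. These values include the gene Lars2, at 33.7% and 12.5% of the counts in Rad21 KO replicates 1 and 2. Technical differences between libraries can also raise them, so they do not show that the samples are separate. The labels name separate samples of each genotype and do not say that they came from separate animals, so p-values measure the spread between these samples, which may be technical. Intervals on counts and shares cover counting error only.

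The counts, rounded to whole numbers as a precaution, were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, and the quasi-likelihood test of genotype with no block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are CPM, counts scaled to a common library total with the TMM factors, and fold changes are the fitted log2 ratio of Rad21 KO over wild type with its standard error. Before the data were examined, 23 gene lists were fixed from general knowledge of thymocytes, cohesin, Mediator, stress and signalling pathways and other cell types that a thymus sort could hold. Each list was tested two-sided with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists, and beside it with an estimated correlation and with fry. With an estimated correlation, camera takes its degrees of freedom from the samples, so it has little power with 2 libraries per genotype. Camera sets a list against all other genes, while fry asks whether the members move on balance in 1 direction, or, in its mixed form, in either.

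The genes to name were also fixed by rule before the data were examined. They are Rad21, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 5 CPM and groups that do not overlap, up to 4 members of each list described (those past the threshold with the largest change, otherwise the most abundant), and every measured member of the cohesin list. A gene that the rule selects is not reported here. Genes named outside this rule are marked as chosen after their values were seen.

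The procedure was tested on simulated counts drawn for the real genes at the real library sizes, with 2 against 2 libraries and 11818 genes tested. It recovered 69 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, and 22 of its 189 calls (11.6%) were genes with no planted change, more than the 5% the threshold aims at. Changes were planted only in genes with a mean of at least 5 CPM, and in far fewer genes than the 1533 called in the data. Recovery of weaker genes, and the share of false calls where more genes change, were not tried. Of 20 random lists in the same simulation 0 were called, at camera's preset correlation, and the 1 list raised on purpose was called. The counts of each simulated gene were drawn independently. The simulation therefore cannot show how often the preset correlation gives false calls for lists whose members vary together.

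Peak lists were deposited by the authors as chromosome, start and end, with no score, height or p-value per peak. The names of the lists point to removal of duplicate reads and to the caller SWEMBL. Coordinates are given in mm9, 1-based. Per the labels' protocols, Rad21 lysates were prepared with more NaCl than NIPBL and Med1 lysates, so the lists differ in more than the antibody. Two-way overlaps of at least 1 bp were counted in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with exact (Clopper-Pearson) 95% binomial intervals. Each overlap was compared with 1000 circular shifts of the list along its chromosomes, a one-sided permutation test whose smallest p is 0.001. Med1 overlap at NIPBL peaks with and without Rad21 was compared by Fisher's exact test, two-sided. Peaks are not replicates, and these tests describe the 3 lists.

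Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, stricter thresholds, an estimated list correlation, a stricter overlap, peaks reduced to 500 bp and local shifts of 20 to 100 kb. Leaving out a library leaves its genotype with a lone sample, which the fit assumes to vary like the other genotype's samples. The assignment of peaks to genes was not run, since it needs an mm9 annotation that was not used here, and gene positions are not printed for the same reason. The RefSeq table of assembly GRCm38.p6 was used for older gene symbols and for the order of genes alone. The files hold no peak scores, so the widest peaks stand in for the highest-scoring ones, chosen after the files were seen.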

Results

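The series asks how cohesin, its loader and Mediator bind the thymocyte genome and what happens to transcription when cohesin is lost. Gene expression was measured by RNA-seq in CD4+CD8+ thymocytes, with 2 wild type and 2 Rad21 KO libraries of 6500819 to 9384505 counts. Of 17849 genes in the table, 12003 passed the filter on low counts. The mitochondrial leucyl-tRNA synthetase gene Lars2 and the noncoding gene Gm15564 were both chosen after their values were seen. Together they took 34.5% and 12.6% of the counts in Rad21 KO replicates 1 and 2, against 5.84% and 7.47% in the wild type replicates. Neither gene passed the threshold (adjusted p = 0.0752 and 0.0536 by edgeR's quasi-likelihood test). Without both genes the totals lay between 6015242 and 6245781 counts.

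Rad21 RNA was reduced in both knockout libraries. It stood at 67.9 and 65.7 CPM in Rad21 KO replicates 1 and 2 and at 271 and 233 in the wild type replicates, a log2 fold change of -1.91 (SE 0.12, n = 2 libraries per genotype, adjusted p = 0.000862 by edgeR's quasi-likelihood test). Counts remained in the knockout, and the table does not show from which part of the gene they came. Among the 18 other tested members of the list of cohesin subunits, loaders and regulators, 0 passed the threshold. The ring subunit Smc1a had a log2 fold change of -0.13 (SE 0.10), Smc3 0.32 (SE 0.10), the loaders Nipbl -0.11 (SE 0.11) and Mau2 0.12 (SE 0.10), and Ctcf, the protein that positions cohesin on DNA, 0.02 (SE 0.12). Among the other members, Stag1 stood at 0.07, Stag2 at -0.07, Wapl at -0.13, Pds5a at 0.03, Pds5b at -0.06, Hdac8 at -0.16, Espl1 at 0.14, Cdca5 at 0.26, Pttg1 at 0.44, Stag3 at 0.71, Sgo1 at -0.52, Esco2 at -0.61 and Esco1 at -0.35. The acetyltransferase gene Esco1 passed only without Rad21 KO replicate 2 (-0.54). The list was not called (adjusted p = 0.315 by camera), and adjusted over the list alone the count was again 1, Rad21.

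Loss of Rad21 was accompanied by changes in both directions. In the knockout, 912 genes were higher and 621 lower, 1533 of 12003 tested, and 432 and 205 of these differed at least 2-fold. Genes that rose included Foxb1, a forkhead transcription factor known from the developing brain, from 3.65 ± 1.69 to 60.4 ± 1.43 CPM (mean ± SD, n = 2), Nr1d1, a nuclear receptor that represses genes of the circadian clock, from 7.98 ± 0.271 to 106 ± 8.42, and Nr4a3, an orphan nuclear receptor induced by antigen receptor signals, by a log2 fold change of 3.32 (SE 0.22). The AP-1 subunit Fosl2 rose by a log2 fold change of 3.65 (SE 0.41), the cyclin gene Ccno by 3.52 (SE 0.34) and Hspg2, which encodes the basement membrane proteoglycan perlecan, by 3.31 (SE 0.25). The laminin chain gene Lama3 fell furthest, from 329 and 271 counts in the wild type libraries to 0 and 1, which is 598-fold lower with a 95% counting interval of 107 to 23674. Angpt1, a ligand of the Tie2 receptor, fell from 27.7 ± 7.61 to 0.897 ± 0.107 CPM, Greb1, a target of the estrogen receptor in other tissues, by 2.69 on the log2 scale (SE 0.15), and the hyaluronan receptor Cd44 from 13.3 ± 0.224 to 1.93 ± 0.606.

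Other large rises were D430041D05Rik (log2 fold change 6.19), the long noncoding RNA Lncpint (3.77), the zinc finger gene Zfp979 (3.69) and the unnamed gene ENSMUSG00000029333 (3.48). The knockout libraries of D430041D05Rik were far apart (30.7 and 444 CPM). Its log2 fold change was 3.25 without Rad21 KO replicate 2, and its call was lost in limma-voom (5.42) and with no filter on low counts. Other large falls were Pakap (-3.40), Gm16316 (-3.38), Rab6b (-2.79), Dact1 (-2.69) and Cpne8 (-2.61). Lncpint, Zfp979, Pakap and Gm16316 overlap other transcripts or belong to families of similar genes, so their counts are uncertain. Gm16316 lost its call without wild type replicate 2 (log2 fold change -2.44). Its call was also lost in DESeq2 (-3.40), limma-voom (-3.98), with the replicate block and with no filter on low counts. All genes named for the size of their change passed an adjusted p of 0.05 by edgeR's quasi-likelihood test.

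The groups did not overlap in any of the 1533 called genes, where chance gives 33.3% of genes and 58.9% of all tested genes did so. Without wild type replicate 2 the calls dropped to 947 (574 higher, 373 lower), without wild type replicate 1 the lower calls dropped to 413, and with no filter on low counts 433 genes were called (285 higher, 148 lower) among 17003 tested.

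**Figure D1:**
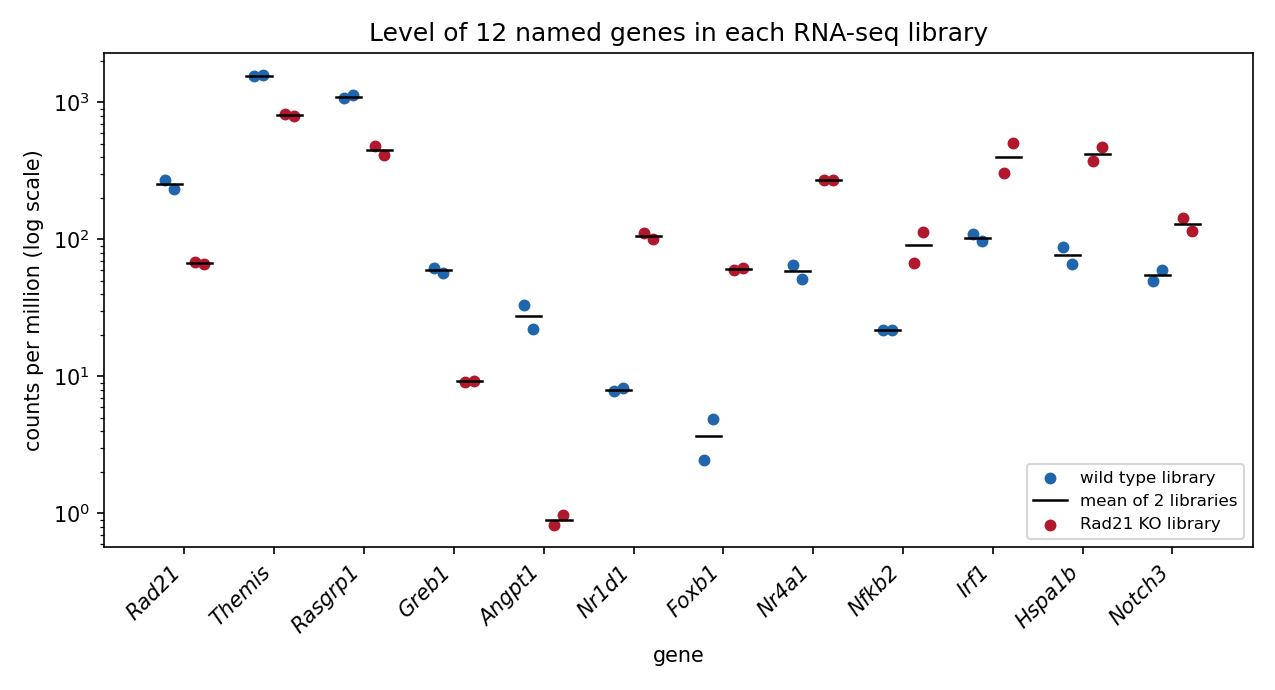
CPM (vertical axis, log scale) of 12 named genes in each of the 2 wild type and 2 Rad21 KO libraries, with points for libraries and a line for the mean of each genotype. The genotypes do not overlap for any of the 12 genes; Rad21 falls from 271 and 233 to 67.9 and 65.7, and Nr1d1 rises from 7.79 and 8.17 to 112 and 99.9.

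Heat-shock and unfolded-protein genes rose in the knockout. Of 16 tested members, 10 were higher and 0 lower, or 16 and 0 adjusted over the list alone, with a median log2 fold change of 0.78. The inducible chaperones Hspa1a and Hspa1b had log2 fold changes of 3.09 (SE 0.26) and 2.46 (SE 0.18), with the reservation that these 2 genes are near-identical copies that share reads. The co-chaperone Hsph1 rose by 1.47 (SE 0.18) and the mitochondrial chaperonin Hspd1 by 1.39 (SE 0.12). The list was called at the preset correlation (adjusted p = 1.12e-15 by camera), while the adjusted p = 0.374 with an estimated correlation.

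NF-κB target genes and immediate early genes, which respond within minutes to hours of receptor signals, moved the same way. Of 16 NF-κB list members, 12 were higher and 0 lower, or 14 and 0 adjusted over the list alone, and the median log2 fold change was 1.17. The cytokine gene Tnf rose from 2.40 ± 0.658 to 19.4 ± 8.01 CPM, and the NF-κB subunits Nfkb2 and Relb rose by log2 fold changes of 2.05 (SE 0.25) and 2.43 (SE 0.43). The chemokine gene Cxcl10 had 74 counts in the knockout and 1 in wild type, 74.2-fold higher with a 95% counting interval of 12.9 to 2970. The NF-κB list had an adjusted p = 1.74e-14 by camera and an adjusted p = 0.374 with an estimated correlation.

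Of 22 immediate early genes, 13 were higher and 1 lower, or 16 and 1 adjusted over the list alone. Nr4a1, which like Nr4a3 is induced by antigen receptor signals, rose from 58.3 ± 9.46 to 271 ± 1.06 CPM, beside Fosl2 and Nr4a3 above. Ier3 rose by a log2 fold change of 4.39 (SE 1.01), with its call lost without Rad21 KO replicate 2 (3.18). The member that fell, chosen after its value was seen, was Fos, with a log2 fold change of -0.53 (SE 0.12, adjusted p = 0.0343 by edgeR's quasi-likelihood test), and its call was lost without Rad21 KO replicate 1 (-0.40) or wild type replicate 2 (-0.46). The list had an adjusted p = 1.08e-14 by camera and an adjusted p = 0.374 with an estimated correlation. The share of Lars2 and Gm15564 counts moved with genotype alongside these 3 lists. With both genes left out, a setting chosen after the data were seen, all 3 lists were still called. That setting removes the counts of these 2 genes alone. It cannot show whether what raised their share also affected the lists.

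Interferon-response genes rose in part. Of 27 tested, 9 were higher, 1 was lower and 17 did not pass, or 16 and 1 adjusted over the list alone. The antiviral gene Rsad2 rose from 3.52 ± 2.27 to 26.7 ± 1.95 CPM and the transcription factors Irf1 from 103 ± 8.55 to 403 ± 141 and Irf9 from 43.5 ± 10.8 to 123 ± 22.7. Usp18, which damps interferon signalling, rose by a log2 fold change of 1.27 (SE 0.23), with its call lost without wild type replicate 2 (1.12). Ifit2, chosen after its value was seen, fell by 0.80 on the log2 scale, with its call lost without wild type replicate 2 (-0.75). The list had an adjusted p = 1.88e-06 by camera and an adjusted p = 0.374 with an estimated correlation.

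The list of early thymocyte genes, which mark the CD4−CD8− stage that precedes double-positive cells, was called upward on few members. Of its 18 genes, 7 were abundant enough to test, of which 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. All 4 that rose are Notch receptors or Notch targets; Notch genes as a group were not a list and were not tested. Notch1 rose from 149 ± 12.6 to 327 ± 55.2 CPM, Notch3 from 54.8 ± 7.14 to 129 ± 19.6 and the Notch target Dtx1 from 6.47 ± 1.03 to 30.5 ± 6.01, and the Notch target Hes1 had 59 counts against 3, 19.7-fold higher with a 95% counting interval of 6.43 to 98.4. Il2ra, a surface marker of that earlier stage, chosen after its value was seen, had a log2 fold change of -0.03 (SE 0.17). The list had an adjusted p = 2.08e-06 by camera and an adjusted p = 0.374 with an estimated correlation.

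Glycolysis genes and genes of NK and γδ T cells completed the lists called upward. Of 15 glycolysis genes, 5 rose and 0 fell, or 7 and 0 adjusted over the list alone, among them the kinase Hk2 (log2 fold change 2.63, SE 0.35), the glucose transporter Slc2a1 (1.34, SE 0.21) and the phosphofructokinase Pfkp (0.91, SE 0.13). The transporter Slc2a3 rose by 0.70 (SE 0.12), with its call lost without wild type replicate 2 (0.65). The list had an adjusted p = 0.000588 by camera and an adjusted p = 0.378 with an estimated correlation. Of 14 NK and γδ T cell genes only Id2, Gzma, Prf1 and Il2rb were abundant enough to test, so the call rests on these 4. The transcriptional regulator Id2 alone passed, rising from 12.9 ± 1.14 to 43.9 ± 0.405 CPM, or 3 of 4 adjusted over the list alone. That list had an adjusted p = 0.00645 by camera and an adjusted p = 0.374 with an estimated correlation.

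Genes that mark double-positive thymocytes were lower in the knockout. Of 27 tested, 10 fell, 1 rose and 16 did not pass, or 12 and 1 adjusted over the list alone, with a median log2 fold change of -0.34. Themis, a regulator of positive selection, fell from 1569 ± 5.04 to 809 ± 18.5 CPM, the surface receptor Slamf6 from 129 ± 10.1 to 67.9 ± 2.49 and the transcription factor Ikzf3 from 396 ± 27.2 to 213 ± 24.2. The gene that rose was Ptcra, the invariant chain of the pre-T cell receptor used before the double-positive stage, with a log2 fold change of 1.07 (SE 0.23), and its call was lost without Rad21 KO replicate 1 (0.84) or wild type replicate 2 (0.99). The list had an adjusted p = 2.85e-06 by camera and an adjusted p = 0.504 with an estimated correlation.

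Apoptosis regulators were lower as a list, with members on both sides. Bmf, which promotes cell death, fell by 1.09 on the log2 scale (SE 0.14), while Bcl2l11, which also promotes cell death, rose from 269 ± 10.6 to 493 ± 111 CPM. Of 18 tested, 3 fell and 1 rose, or 7 and 1 adjusted over the list alone, and the other 2 that fell were Apaf1 (log2 fold change -0.43), whose call was lost on leaving out any of the 4 libraries (-0.38 to -0.47), and Cflar (-0.53), whose call was lost without Rad21 KO replicate 2 (-0.34) or wild type replicate 2 (-0.48). The list had an adjusted p = 0.0127 by camera and an adjusted p = 0.374 with an estimated correlation. Of the 23 lists, 9 were called at the preset correlation and 0 with an estimated correlation, where 0 also passed an unadjusted p of 0.05. The estimated form has few degrees of freedom with 2 libraries per genotype, so it cannot decide whether the preset calls hold. Fry called 0 in 1 direction (smallest adjusted p = 0.0641) and 20 in its mixed form.

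T cell receptor signalling genes and genes of mature single-positive cells were not called as lists (adjusted p = 0.852 and 0.907 by camera), yet members changed strongly in both directions. The calcium-dependent transcription factor Nfatc2 rose from 8.74 ± 1.74 to 50.4 ± 13.3 CPM and Nfatc1 and Bcl10 by log2 fold changes of 0.67 (SE 0.11) and 1.07 (SE 0.17), while Rasgrp1, the exchange factor that links the receptor to Ras, fell from 1103 ± 40.9 to 448 ± 48.7. Of 28 signalling genes, 4 rose and 4 fell, or 4 and 5 adjusted over the list alone. Of 21 maturation genes, 3 rose and 3 fell, or 6 and 6 adjusted over the list alone. The lymph node homing receptor Ccr7 rose from 4.40 ± 0.736 to 36.1 ± 1.85 CPM and Foxo1 from 47.1 ± 18.1 to 141 ± 27.7, while Tox, which CD4 lineage development requires, fell from 183 ± 2.72 to 79.8 ± 4.27. Other members past the threshold, chosen after their values were seen, were Cd28 (0.51), Lck (-0.48), Cd2 (-0.47) and Cd5 (-0.42) among signalling genes, and Klf2 (1.13) beside Cd44 among maturation genes. Leaving out any of the 4 libraries ended the calls of Lck (-0.41 to -0.55), Cd2 (-0.43 to -0.52) and Cd5 (-0.37 to -0.47), and each of 3 libraries ended that of Cd28 (0.46 to 0.55).

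Genes of the p53 response had 6 members higher and 1 lower of 26, or 7 and 3 adjusted over the list alone, and narrowly missed the threshold as a list (adjusted p = 0.0561 by camera). Pmaip1, a death-promoting target of p53, rose by a log2 fold change of 2.09 (SE 0.25) and the kinase Plk2 by 1.94 (SE 0.21). Perp rose by 2.38 (SE 0.50), with its call lost without Rad21 KO replicate 2 (2.24) or wild type replicate 2 (1.91), and Plk3 by 1.32 (SE 0.25), with its call lost without wild type replicate 1 (1.19). Of 26 genes each, the list of DNA replication had 2 higher and 0 lower, or 1 and 0 adjusted over the list alone, and the list of mitosis 1 higher and 2 lower, or 1 and 2 adjusted over the list alone (adjusted p = 0.852 and 0.868 by camera). The licensing factor Cdt1 rose by 0.86 (SE 0.16) and the replication clamp Pcna by 0.54 (SE 0.13), the spindle protein Prc1 rose by 0.90 (SE 0.19), and the kinetochore genes Cenpe and Cenpf had log2 fold changes of -0.74 (SE 0.17) and -0.72 (SE 0.14). In this group the call of Pcna was lost without Rad21 KO replicate 2 (0.39) or wild type replicate 2 (0.49), that of Prc1 without Rad21 KO replicate 2 (0.73) or wild type replicate 1 (0.71), that of Cenpe without Rad21 KO replicate 1 (-0.58) or either wild type replicate (-0.70 and -0.80), and that of Cenpf without wild type replicate 1 (-0.64).

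The list of Mediator genes was not called in a shared direction, with Med30 lower at a log2 fold change of -0.92 (SE 0.16), Med13l higher at 0.37 (SE 0.09) and 30 of 32 not past the threshold (adjusted p = 0.958 by camera). Adjusted over the list alone, Med30 alone passed, and the call of Med13l was lost on leaving out any of the 4 libraries (0.36 to 0.39). Nuclear genes of oxidative phosphorylation had 0 of 25 members called, also adjusted over the list alone (adjusted p = 0.868 by camera), with a median log2 fold change of -0.03 and the ATP synthase subunits Atp5a1 and Atp5b at -0.03 and 0.06. In the list of gene clusters with known cohesin dependence, 3 of 24 members were abundant enough to test and 0 were called, also adjusted over the list alone (adjusted p = 0.868 by camera); these were Hoxa7 (-1.56), Myc (0.35) and Rad50 (0.07). Of 4 tested Y-linked genes, Kdm5d had a log2 fold change of -0.80 (SE 0.11) and Uty -0.49 (SE 0.13), or 3 lower adjusted over the list alone, and the list itself was not called (adjusted p = 0.0537 by camera). The call of Uty was lost without Rad21 KO replicate 1 (-0.39) or wild type replicate 2 (-0.39).

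The lists of myeloid and dendritic, B cell, erythroid and thymic stroma markers were not called. Of 8 tested myeloid and dendritic genes, 0 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.561 by camera), and that 1 was the integrin gene Itgam, at 8.48 ± 0.189 CPM in the knockout and 20.7 ± 4.57 in wild type, whose call was lost without wild type replicate 2 (log2 fold change -1.05). Of 6 B cell genes and 6 erythroid genes 0 passed, also adjusted over the list alone (adjusted p = 0.868 for each by camera), with Cd74 at a log2 fold change of -0.03 and Ighm at 0.31. The carbonic anhydrase gene Car2, an erythroid member at -1.35, passed only without Rad21 KO replicate 1 (-1.88). Among 6 thymic stroma genes the adhesion molecule Epcam rose from 1.24 ± 0.377 to 10.6 ± 1.58 CPM and Pecam1 fell from 149 ± 2.18 to 99.5 ± 4.29, also the count adjusted over the list alone, and the list was not called (adjusted p = 0.902 by camera). Median, mean and camera's direction differed in sign for the lists of replication, erythroid, cohesin-dependent cluster, maturation, Mediator, receptor signalling and stroma genes, none of which was called.

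**Figure D2:**
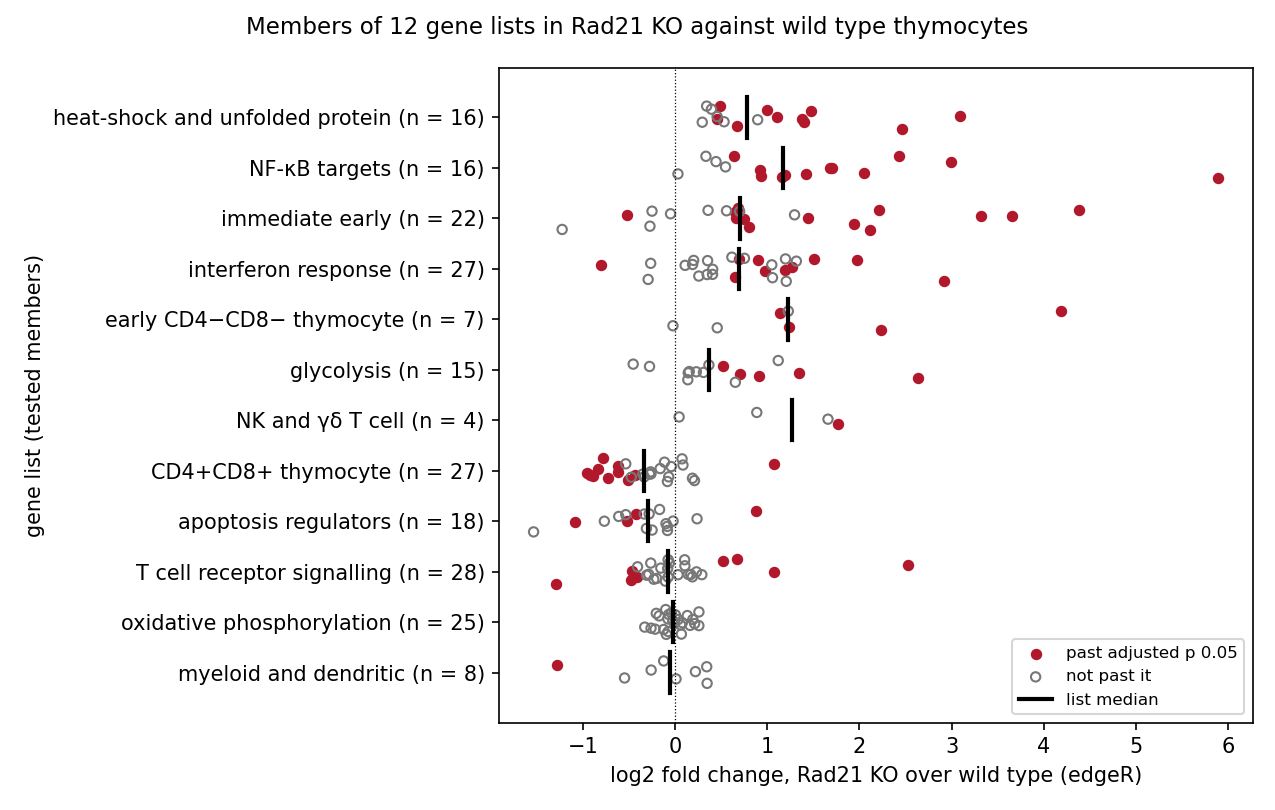
Log2 fold change of Rad21 KO over wild type (horizontal axis) for each tested member of 12 of the 23 gene lists, with filled points past an adjusted p of 0.05, open points not past it, and a bar at the list median. Medians run from -0.34 for double-positive thymocyte genes to 1.27 for the 4 NK and γδ T cell genes, and 1.17 for NF-κB targets. The points of Cxcl10 (rightmost of the NF-κB list) and Hes1 (rightmost of the early thymocyte list) are fitted values that rest on 1 and 3 wild type counts.

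The Rad21, NIPBL and Med1 peak lists of wild type thymocytes overlapped far more than shifted lists did. The lists held 27207 Rad21, 51994 NIPBL and 15112 Med1 peaks, covering 8.77, 20.9 and 5.96 Mb, with 1 ChIP library per protein and so no replicate check. Of the Rad21 peaks, 10193 (37.5%, exact 95% interval 36.9 to 38.0) overlapped a NIPBL peak, against 1.52% on average after circular shifts, a 24.6-fold excess. Of the Med1 peaks, 5724 (37.9%, 37.1 to 38.7) overlapped a NIPBL peak, a 22.7-fold excess, and 1699 (11.2%, 10.7 to 11.8) a Rad21 peak, a 13.4-fold excess. In the other direction, 19.8% of NIPBL peaks overlapped Rad21, 11.2% of NIPBL peaks overlapped Med1, and 6.41% of Rad21 peaks overlapped Med1. Each overlap was above all of the 1000 shifts (one-sided permutation p = 0.001, the smallest they can give). With shifts of 20 to 100 kb only, which keep peaks in their neighbourhood, the excess was 8.31-fold for Rad21 with NIPBL, 8.60-fold for Med1 with NIPBL and 5.46-fold for Med1 with Rad21.

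Among the Med1 peaks, 1153 (7.63%) overlapped both other proteins, 4571 NIPBL alone, 546 Rad21 alone and 8842 (58.5%) neither. The widest NIPBL and Med1 peaks coincided on chromosome 17 in mm9, from 39979831 to 39985886 and 39985887, a stretch that also held 5 Rad21 peaks. The widest Rad21 peaks lay on chromosome 3 from 21834303 to 21835946, where NIPBL and Med1 each had a peak, and from 21974666 to 21976174, where NIPBL had one. The next widest peaks of the other lists were a NIPBL peak on chromosome 1 from 88420978 to 88425510, with 1 Rad21 peak, and a Med1 peak on chromosome Y from 2851185 to 2857233, with 5 Rad21 and 7 NIPBL peaks. Genes and repeats at these positions were not looked up. The input libraries were not analysed here and no artifact-prone regions were removed, so the widest peaks are not shown to be sites of binding. For the same reason, artifacts common to the lists are not excluded from the overlaps.

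**Figure D3:**
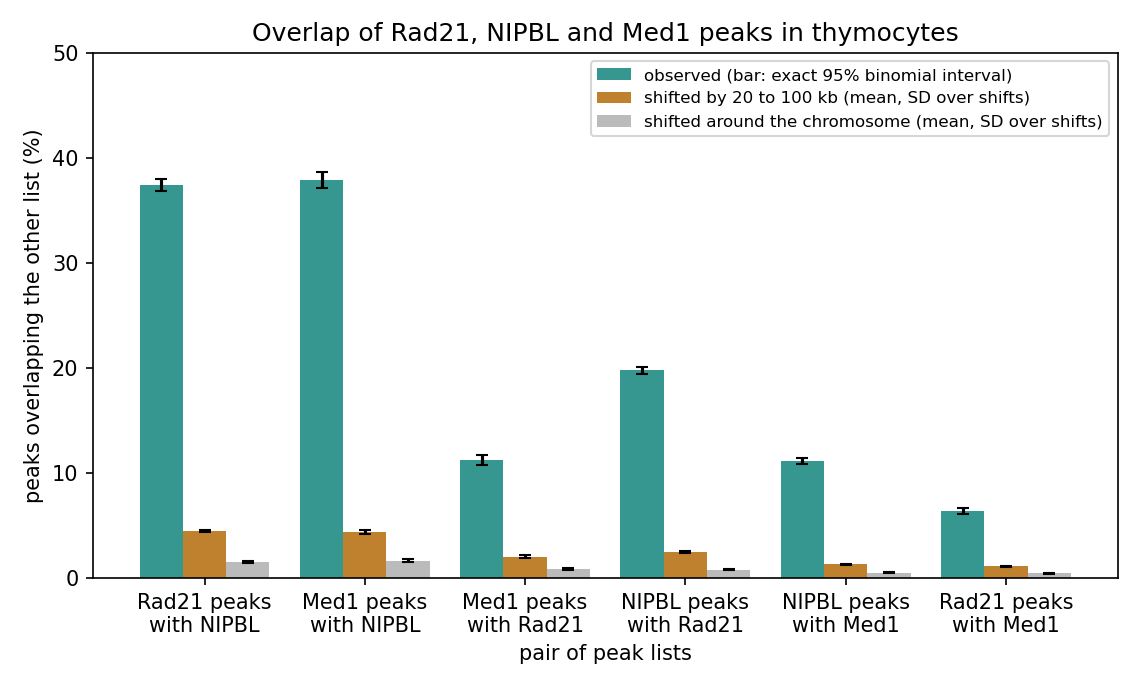
Percentage of peaks of a list that overlap a peak of another (vertical axis) for the 6 ordered pairs of Rad21, NIPBL and Med1, as observed with exact 95% binomial intervals, and as the mean with SD over shifts of 20 to 100 kb and over circular shifts around the chromosome. Observed shares run from 6.41% for Rad21 peaks with Med1 to 37.9% for Med1 peaks with NIPBL, and the circular shifts average 0.459% and 1.67% for the same pairs.

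Med1 was found slightly more often at NIPBL peaks that also carried Rad21. Of 10295 NIPBL peaks with Rad21, 12.9% (exact 95% interval 12.2 to 13.5) overlapped Med1, and of 41699 without Rad21, 10.8% (10.5 to 11.1) did, an odds ratio of 1.22 (1.14 to 1.30, two-sided Fisher's exact test p = 4.4e-09). Within classes of width, the association was found at narrow NIPBL peaks alone. The 5 classes of NIPBL peak width were chosen after the data were seen. The odds ratio was 1.43 in the narrowest (154 to 234 bp) and 1.39 and 1.31 in the next classes. It was 0.973 and 0.959 in the widest (341 to 526 and 527 to 6056 bp). Med1 was found at 12.3% and 22.6% of peaks in these widest classes, against 6.59% in the narrowest class. Rad21 was also most frequent in the widest class, at 25.1% of peaks against 20.1% in the narrowest. Width can therefore raise the pooled odds ratio of 1.22, by an amount that was not tested. With each list restricted to its wider peaks, also a setting chosen after the data were seen, the odds ratio turned to 0.898 (0.784 to 1.03, Fisher's exact test p = 0.13).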

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

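The settings without Lars2 and Gm15564 and with the wider peaks of each list, and the classes of NIPBL width, were chosen after the data were seen, and the others before. The Rad21 log2 fold change kept its direction and its call under all settings run, between -1.80 without wild type replicate 1 and -2.02 without wild type replicate 2. Against 1533 calls, edgeR with DESeq2 size factors gave 1518, DESeq2 1267, limma-voom 1490 and the fit without Lars2 and Gm15564 1521. With no filter on low counts 433 genes were called (285 higher, 148 lower), all among the 1533, from 17003 genes tested in place of 12003, with 3479 against 3532 at an unadjusted p under 0.05. At an adjusted p under 0.01, 434 genes passed, and 637 passed with a 2-fold minimum. Leaving out each library in turn gave 947 to 1438 calls, 574 to 880 higher and 373 to 558 lower, the lowest without wild type replicate 2, in fits that have fewer samples.

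The replicate numbers gave no sign of pairing the samples: deviations of same-numbered libraries correlated at 0.0385. With 2 pairs only, this cannot exclude a pairing. The replicate block gave 1025 calls, 644 higher and 381 lower, in a fit with fewer residual degrees of freedom, left 9 lists called, and changed the side of the threshold for 9 of the 108 named genes. Under no setting did a called named gene turn direction. Of the 75 called in the main setting, 29 lost their call with no filter, 4 with DESeq2 (Gm16316, Apaf1, Cenpe and Perp), 3 with limma-voom (Gm16316, D430041D05Rik and Ier3) and 5 to 12 without a library.

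Of 9 lists called, 9 were called with DESeq2 size factors, and 9 kept their direction with each library left out in turn. With no filter or without Lars2 and Gm15564, 10 were called (the Y-linked list added, adjusted p = 0.0371 and 0.0481 by camera). With an estimated correlation 0 were called. That form widens the null for lists whose members vary together, and with 2 libraries per genotype it also has few degrees of freedom. Which of these ended the calls was not tested. Requiring 50% of the shorter peak gave overlaps of 35.7% (Rad21 with NIPBL), 32.9% (Med1 with NIPBL) and 9.34% (Med1 with Rad21); peaks reduced to 500 bp gave 38.2%, 38.8% and 12.8%; wider peaks gave 25.8%, 26.8% and 5.50%, where each list has fewer partners to meet. With wider peaks the odds ratio of Med1 at NIPBL peaks with Rad21 turned to 0.898; the classes of NIPBL width show the same change, and its cause was not tested. The score threshold on peaks and the tests of peaks near genes were not run, since the lists have no scores and no mm9 annotation was used here; pseudocounts did not apply to counts. With 2 libraries per genotype, 2-fold changes were recovered less often than 4-fold ones in simulation (69 against 98 of 100), so a gene that was not called is not shown to be unchanged.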

Other observations

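The tests of carry-over, of myeloid cells, of handling, of noise between libraries of one genotype, of circadian phase and of glucocorticoids were chosen after the values they bear on had been seen; the tests of rho for the effect of regions and for shared reads were written before their result was known. Clock genes were in no list fixed beforehand, and their names were chosen after their values were seen. The clock repressors Nr1d1 and Nr1d2 rose by log2 fold changes of 3.73 (SE 0.15) and 2.30 (SE 0.11), the period gene Per1 by 1.87 (SE 0.13), Dbp by 1.58 (SE 0.14), Ciart by 2.05 (SE 0.26), Npas2 by 3.12 (SE 0.25) and Rora by 2.72 (SE 0.14), all by edgeR's quasi-likelihood test and with each library left out in turn. Per3 rose by 1.63 (SE 0.31) and lost its call without wild type replicate 2 (1.49), and Per2 (1.47, SE 0.35) lost it without Rad21 KO replicate 2 (1.10) or either wild type replicate. Arntl (0.42) lost its call on leaving out any of the 4 libraries (0.40 to 0.44), and Clock and Cry1 had log2 fold changes of 0.28 and -0.30 and were not called.

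Several pairs of adjacent genes changed together, also chosen after their values were seen. Dad1 and Abhd4, which lie beside the T cell receptor alpha locus, rose by log2 fold changes of 1.41 (SE 0.11) and 2.24 (SE 0.23). That pair was not among those ranked for a gap of more than 10 kb, so shared reads are not excluded for it. The pairs given next lie more than 10 kb apart. Hid1 and Cdr2l had values of -2.18 and -1.59, Zfp516 and Tshz1 1.29 and 1.31, and Map3k20 and Cdca7 -1.41 and -1.51, with Cdr2l not called without wild type replicate 2 (-1.51). Around Rad21 itself, the next gene on one side, Med30, was lower (-0.92) and so was Trps1 (-1.98), 3 places away on the other side, while the nearer genes Utp23 (0.06) and Eif3h (-0.04) and, beyond Med30, Ext1 (-0.23) were not called. Of the 100 tested genes nearest to Rad21 16 (16.0%) were called, against 1451 of 11200 others (Fisher's exact test p = 0.369); this test was chosen after gene values were seen, and the number 100 replaced a larger one after a first result was seen. Med1 peaks were denser on chromosomes 17, 11 and 1 (15.6, 10.3 and 9.30 per Mb) than on the median autosome (5.50 per Mb), at 2.84, 1.87 and 1.69 times that median. Rad21 peaks on these chromosomes were at 1.36, 1.83 and 0.909 times their own median and NIPBL peaks at 1.55, 2.06 and 0.890 times. On chromosome Y, over a span of 2.56 Mb, Med1, Rad21 and NIPBL peaks were at 8.33, 3.49 and 1.75 times their medians. Whether repeats or input signal raise these densities was not checked.

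The rise of heat-shock, NF-κB and immediate early genes is the pattern a biologist would first ask about. Ribosomal RNA carry-over, for which the large Lars2 share of Rad21 KO replicate 1 is a candidate source, would put the larger rise there. The 54 tested members were instead higher in replicate 2 by a median of 0.27 on the log2 scale (bootstrap 95% interval over genes 0.14 to 0.33). This sets 1 library against 1, and the interval does not cover the spread between libraries. Both knockout libraries had a larger share of Lars2 and Gm15564 (34.5% and 12.6%) than both wild type libraries (5.84% and 7.47%). A difference in carry-over between the genotypes therefore cannot be told apart from the knockout. Myeloid or dendritic cells, which the CD4 and CD8 sort should remove, would bring their own transcripts, but the 8 tested markers had a median of -0.0601 (-0.55 to 0.34) against 1.17 (0.64 to 1.70) for NF-κB targets, with Lyz2 at 2.33 and 5.70 CPM in the knockout and 3.69 and 2.63 in wild type. Longer handling before lysis cannot be told apart from genotype, since no label records handling: the 10 genes taken as handling markers had a median of 0.67 (-0.25 to 1.32), with 5 higher and Fos lower, but all 10 belong to the immediate early list, so this value restates the pattern and is no separate test of it. Handling, carry-over that differs by genotype, and an effect of Rad21 loss itself all stay open.

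Neighbouring genes may change together because cohesin loss acts on regions; this is a hypothesis, and the effect is small. Across 3734 adjacent pairs more than 50 kb apart, Spearman's rho of the log2 fold changes was 0.0653, above all of 1000 permutations within 10 expression classes (highest 0.0504), with gene order known for 94.2% of tested genes and similarly named neighbours left out; these are correlations across genes, which are not independent replicates. Shared reads of overlapping or abutting genes do not account for all of it, since pairs more than 10 kb apart kept a rho of 0.0676 (highest permuted 0.0411), though closer pairs reached 0.169. For noise between libraries, the test set first was the wild type difference alone (rho -0.0040 at more than 10 kb). The difference between the Rad21 KO libraries and the split by distance were added after the values were seen. The knockout difference gave 0.0352 at more than 10 kb, over 50% of that of genotype, so that noise cannot be told apart there. At more than 50 kb it gave 0.0095, which argues against noise between libraries of the same genotype. Technical differences that go with genotype would not show in either difference, and were not tested. Neighbours that share regulation in any comparison would give the same sign, and that was not tested.

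The clock genes may reflect harvest at another hour or hormone exposure. Another circadian phase would lower the genes of the opposite phase, but with 4 such genes (Arntl, Npas2, Clock and Cry1) the median was 0.35 with an interval of -0.30 to 3.12, against 1.75 (1.47 to 2.30) for 8 genes of the other phase, so a shift of phase cannot be told apart from the genotype. The clock genes Nfil3 and Cry2, which were in neither set, rose by log2 fold changes of 1.62 and 0.76. Glucocorticoid exposure is a candidate explanation that narrowly met the bound set for it: 12 tested genes induced by glucocorticoids had a median of 0.52 (0.07 to 0.74), with 6 higher and 0 lower. Without Dusp1 and Nfkbia, which other lists also hold, the median was 0.38 (-0.14 to 0.69), and the specific targets Tsc22d3 and Fkbp5 had log2 fold changes of 0.28 and -0.14 and were not called. A direct effect of Rad21 loss on these genes stays open and was not tested.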
